A study of Mus musculus with 6 samples.

How the data were processed

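The series held 6 RNA sequencing libraries of pancreatic islets from C57BL/6 mice aged 8 weeks on normal chow, 3 labelled Mettl3 flox/flox and 3 labelled as a β-cell knockout of Mettl3. Groups and replicate numbers were taken from the sample titles and genotype labels. The labels name the Cre of the knockout group as RIP-Cre, and no library is labelled with Cre alone, so effects of Cre and of the deletion were not separated. They do not say whether islets of several mice were pooled or which exons the floxed allele removes. They list the libraries as separate samples without naming animals, so p-values measure the spread between these libraries and would be too small if replicate 3 of a group held RNA pooled from the others.

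Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 were used with the GRCm38 assembly at patch 6. The role and settings of each tool are not given in the sources used here, and neither is the strandedness of the libraries. Per the labels' protocols, total RNA was extracted and Illumina libraries were made by a standard protocol. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, relative to library size) for 54556 genes, with gene lengths and coordinates per the file headers. Of the gene identifiers, 53620 were found in the reference table used here, and 755 genes had no symbol. No other per-sample column was left unused (0 columns).

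FPKM multiplied by gene length gave whole multiples of 1 step per library. After division by that step, 100% of the values in each library lay within 0.1 of a whole number, with a largest distance of 0.0538. These whole numbers were taken as reads, the step being the median of the 300 lowest values above 0. They summed to between 16398862 and 18387313 reads per library. The divisor behind the deposited FPKM was 0.855 to 0.885 times the library's own total in the flox/flox group and 1.13 to 1.17 times in the other group. Divided by the library's median-of-ratios factor it came to 17269543 or 17269544 in every library, so the deposited values already carried a median-of-ratios scaling. That scaling sets the typical gene to no change and leaves the total RNA per cell unmeasured. Counting error was small for abundant genes, and a count of 0 in 1 library allowed up to 3 reads. Such floors cover counting error only.

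Values were scaled by median of ratios over the 19623 genes above 0 in all 6 libraries, which changed nothing because the factors were 1. Genes with a mean of at least 1 scaled FPKM were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) on log2(scaled FPKM + 0.5), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are differences on that log2 scale, which understates the change of genes with low values, and errors are standard errors of the model. In total 34 gene lists were fixed before the data were examined and tested with camera in limma with an inter-gene correlation of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry were run as alternatives. Of 806 list entries, 803 were in the table. Lists of enterocyte, intestinal secretory-cell, B-cell and plasma-cell, T-cell and intestinal smooth-muscle markers were written after the values were seen and were not entered in camera.

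The genes named in the text followed a rule fixed before the data were examined. It takes Mettl3, Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Pdx1, Mafa, Nkx6-1, Slc2a2 and Ucn3 always. It adds the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 scaled FPKM and groups that did not overlap, leaving out symbols made of Gm and a number or naming a Rik clone. For each list described it takes the 2 to 4 members past the threshold with the largest absolute log2 fold change. Genes named outside the rule are said to have been chosen after their values were seen.

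The test was tried on simulated data built from these libraries with 200 of 13438 genes changed. It recovered 78% of genes changed 1.5-fold, 96% at 2-fold, 95.9% at 4-fold and 100% at 8-fold, with 7 false calls, and called 0 genes when none was changed. Every gene was simulated with the same dispersion (variation beyond counting error) of 0.00407, the median over genes with many reads, and with independent libraries. These rates therefore do not carry over to genes that varied more between libraries, or to replicates that are not independent. The 200 changed genes rose or fell at random, and were far fewer than the 4935 of 14497 called in the real data. The simulation therefore does not test the median-of-ratios scaling when many genes change. Within each group, reads of every pair of libraries differed by 7.00 to 32.6 times sampling noise (chi-square per degree of freedom), so no library was a copy of another's reads. Separate preparations of the same RNA could differ as much, so this does not show that the libraries are independent. Alternatives covered the pseudocount, the filter, the scaling, a replicate block, the variance trend, library weights, protein-coding genes alone and leaving out each library. Scaling to each library's own reads, voom on the recovered reads, leaving out 2 libraries with many intestinal reads and leaving out intestinal and lymphoid genes were added after seeing the data. Gene positions are those of the deposited table, and overlaps and exons came from GENCODE release vM21 on the same assembly. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps. Single-gene results for 3 members of the lists are not reported here.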

Results

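RNA from whole pancreatic islets was sequenced to ask how gene expression differs when Mettl3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA, is deleted in β cells. There were 3 libraries from Mettl3 flox/flox mice and 3 from flox/flox mice with RIP-Cre (Cre under a rat insulin promoter), labelled as β-cell knockouts, all at 8 weeks of age. Recovered reads came to 16398862 to 17691055 per flox/flox library and 16719393 to 18387313 per library labelled knockout. Spearman correlations across genes were 0.959 to 0.971 within the flox/flox group, 0.937 to 0.969 within the libraries labelled knockout and 0.855 to 0.894 between them.

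Mettl3 itself was not lower in the libraries labelled knockout. The gene, ENSMUSG00000022160 on the minus strand of chromosome 14 from 52294841 to 52305128 (GRCm38), had 3.41 ± 0.52 scaled FPKM in the flox/flox libraries and 4.14 ± 0.0697 in the libraries labelled knockout (SD, n = 3 each). It had 263, 212 and 296 reads in flox/flox replicates 1 to 3, and 430, 417 and 437 reads in the libraries labelled knockout. The log2 difference was 0.25 ± 0.11 (SE, limma adjusted p = 0.12), so it did not pass the threshold, and its direction was opposite to a loss of the transcript. Reads summed over the whole gene cannot show the removal of some exons, and whole islets hold cells other than β cells. The expression values therefore do not check the genotype, and every direction given here is that of libraries labelled knockout against flox/flox libraries. The annotated end of the gene overlaps Tox4 on the opposite strand.

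Genes of mature β cells were lower in the libraries labelled knockout. Slc2a2, which encodes the glucose transporter GLUT2, fell from 131 ± 2.32 to 27.1 ± 0.983 scaled FPKM (SD, n = 3 each), and Mafa, a transcription factor of mature β cells, fell from 285 ± 38.4 to 42.5 ± 12.7. Ins1 fell from 71100 ± 6038 to 21187 ± 563.9 scaled FPKM, and Ins2 from 196850 ± 25060 to 80157 ± 3847. Pdx1 fell from 62.3 ± 4.76 to 34.5 ± 3.32, Nkx6-1 from 113 ± 8.24 to 70.01 ± 3.39 and Ucn3, a peptide of mature β cells, from 330.1 ± 11.6 to 189.9 ± 11.01. Iapp, the amyloid peptide co-secreted with insulin, was at 16564 ± 1113 and 15390 ± 2817 scaled FPKM, and its log2 difference of -0.12 ± 0.22 (SE) did not pass (adjusted p = 0.705).

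On the log2 scale Slc2a2 fell by 2.26 ± 0.06 (SE, limma adjusted p = 1.43e-05), Mafa by 2.77 ± 0.21 (adjusted p = 0.000361) and Ins1 by 1.74 ± 0.25 (adjusted p = 0.00307). Ins2 fell by 1.29 ± 0.37 (adjusted p = 0.0362), a call lost in each of the 6 fits that left out 1 library (adjusted p = 0.0607 to 0.177). Quantile normalization gives genes of the same rank the same value, so it sets the differences of Ins1 and Ins2, ranked alike in all libraries, to 0 by construction. It moved Iapp to 0.75 (adjusted p = 0.00517). Ins1 and Ins2 have nearly identical coding sequences, so their reads may be split unevenly and the share of each is uncertain. Together they took 25.8% to 31.6% of reads in the flox/flox libraries and 14.4% to 15.1% in the others (exact two-sided permutation p = 0.10, the smallest that 3 against 3 allows).

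The other islet hormones did not pass in the main fit. Gcg, from α cells, was at 7397 ± 1646 and 8144 ± 1820 scaled FPKM in flox/flox and labelled-knockout libraries (adjusted p = 0.702). Ppy, from PP cells, was at 2255 ± 589.3 and 2972 ± 245.8 (adjusted p = 0.158), and passed at a log2 difference of 0.84 with own-total scaling and 1.09 with quantile normalization (adjusted p = 0.0103 and 0.000838), against 0.43 in the main fit. Sst, from δ cells, was at 4717 ± 260.3 and 3221 ± 809.9 (adjusted p = 0.0645), and passed as lower in 7 alternatives (adjusted p = 0.00563 to 0.0487). Quantile normalization also passed Gcg, at 0.98 (adjusted p = 0.0309).

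**Figure D1:**
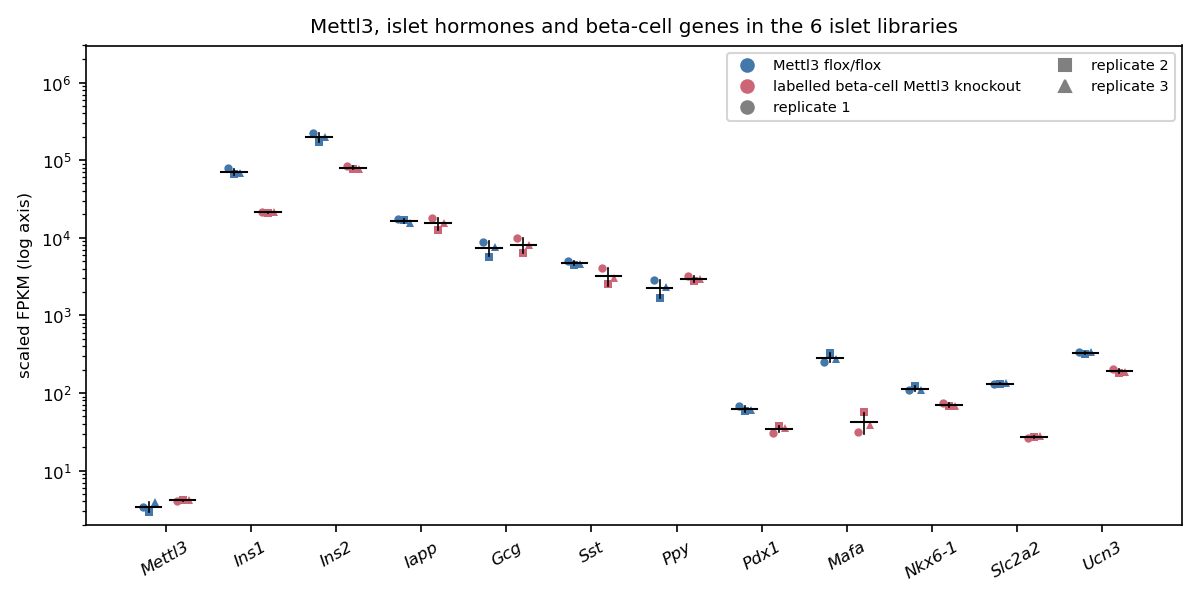
Scaled FPKM (log axis) of Mettl3, the islet hormones and β-cell genes in each library, with flox/flox libraries in blue, libraries labelled knockout in red, a marker shape per replicate, and horizontal and vertical lines for the mean and SD (n = 3 each). Slc2a2 and Mafa stand at 27.1 and 42.5 in the libraries labelled knockout against 131 and 285, while the Iapp points of the groups overlap.

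Of 30 tested genes in the β-cell identity list, 16 fell, 4 rose and 10 did not pass (17 and 4 adjusted over the list alone), with a median log2 difference of -0.37. Trpm5, a cation channel, fell by 3.64 ± 0.12 (SE, adjusted p = 2.14e-05). The list as a whole was lower (camera adjusted p = 6.81e-05), a call lost with an adjusted p = 0.529 with an estimated correlation, and with quantile normalization (adjusted p = 0.0531). In the list for stimulus-secretion coupling and exocytosis, 14 of 35 genes fell, 2 rose and 19 did not pass (15 and 2 adjusted over the list alone). Nnat fell by 1.85 ± 0.11 and Sytl4, a granule docking protein, by 1.72 ± 0.09 (adjusted p = 0.000156 and 8.56e-05). That list had a camera adjusted p = 0.000925, and an adjusted p = 0.529 with an estimated correlation.

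Several endocrine progenitor and dedifferentiation markers were higher in the libraries labelled knockout. Aldh1a3, a retinaldehyde dehydrogenase used as a marker of dedifferentiated β cells, rose from 0.893 ± 0.356 to 20.3 ± 2.70 scaled FPKM (SD, n = 3 each; log2 difference 3.92 ± 0.19 SE, adjusted p = 7.47e-05). Neurog3, the transcription factor of endocrine progenitors, rose from 2.58 ± 0.10 to 9.92 ± 0.844 (1.75 ± 0.08, adjusted p = 7.47e-05), and Serpina7 from 2.25 ± 0.402 to 64.9 ± 14.2 (4.56 ± 0.18, adjusted p = 3.55e-05). Npy went the other way and fell by 1.76 ± 0.33 (adjusted p = 0.00887). Of 16 tested members 7 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone. The camera adjusted p was 0.0327, and the call was lost with an adjusted p = 0.529 with an estimated correlation, without flox/flox replicate 1 (adjusted p = 0.0533) and with own-total scaling (adjusted p = 0.295).

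Genes of the m6A machinery and genes normally kept low in β cells were also higher. Of 21 m6A genes 8 rose, 0 fell and 13 did not pass, as when adjusted over the list alone. Rbm15, an adaptor of the writer complex, rose by 0.96 ± 0.08 and Ythdf2, a reader, by 0.79 ± 0.08 (SE, adjusted p = 0.000386 and 0.00101). The camera adjusted p was 0.0327, and the call was lost with an adjusted p = 0.55 with an estimated correlation and without flox/flox replicate 1, flox/flox replicate 2 or labelled-knockout replicate 3 (adjusted p = 0.0615, 0.0514 and 0.0658), or without labelled-knockout replicates 2 and 3 together (adjusted p = 0.113). Of 19 disallowed genes 5 rose, 0 fell and 14 did not pass, as when adjusted over the list alone. Ldha, a lactate dehydrogenase subunit, rose (adjusted p = 0.029), and its call was lost without any of the 3 flox/flox libraries or without labelled-knockout replicate 3 (adjusted p = 0.0573 to 0.0872). Its level was 12.8, 43.5 and 25.5 scaled FPKM in labelled-knockout replicates 1 to 3, the same order as the enterocyte markers given below. The cells these reads came from are therefore not known. The list had a camera adjusted p = 0.0327, and an adjusted p = 0.806 with an estimated correlation. It was also lost without flox/flox replicate 1 or labelled-knockout replicate 2 (adjusted p = 0.0533 and 0.101), with quantile normalization, own-total scaling or fry (adjusted p = 0.0814, 0.288 and 0.18), and without labelled-knockout replicates 2 and 3 (adjusted p = 0.165).

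Transcripts of lymphocytes were far higher in the libraries labelled knockout. All 14 tested lymphocyte markers rose, likewise adjusted over the list alone, with a median log2 difference of 2.88, or 3.35 with the 1 member without a flox/flox read set at its bound. Cd79b, of B cells, rose by 5.29 ± 0.17 (SE, adjusted p = 1.92e-05). The camera adjusted p was 2.39e-11, and the call was lost with an adjusted p = 0.308 with an estimated correlation. Immunoglobulin genes took 0.00232% to 0.00356% of reads in flox/flox libraries and 0.192% to 0.291% in the others, and 120 of them rose. Igha, the constant region of IgA, rose from 2.43 ± 2.14 to 315.6 ± 109.5 scaled FPKM, Igkc from 11.2 ± 3.69 to 1016 ± 230.9 and Jchain from 0.67 ± 0.127 to 100.7 ± 41.6 (SD, n = 3 each). Igkv10-96, Igkj5 and Igkj4 had 0 reads in the 3 flox/flox libraries and were at least 181-fold, 22.9-fold and 19.2-fold higher, against a floor of 3 reads over that group. Reads of such gene families can be shared between members, so single members are uncertain.

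Intestinal transcripts rose in the same libraries. Fabp2, a fatty-acid binding protein of enterocytes, went from 0.0956 ± 0.166 to 73.6 ± 68.8 scaled FPKM and Rbp2, an enterocyte retinol-binding protein, from 0.139 ± 0.118 to 77.5 ± 69.4 (SD, n = 3 each; log2 difference 6.28 ± 0.93 and 6.26 ± 0.91 SE, adjusted p = 0.00361 and 0.00334). Fabp2 had 180, 2754 and 1321 reads in labelled-knockout replicates 1 to 3. In a list written after the values were seen, 23 of 24 enterocyte markers rose. The enterocyte list came to 264 to 281 CPM (its reads scaled to library size) in flox/flox libraries, and to 868, 3226 and 1892 CPM in labelled-knockout replicates 1, 2 and 3.

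**Figure D2:**
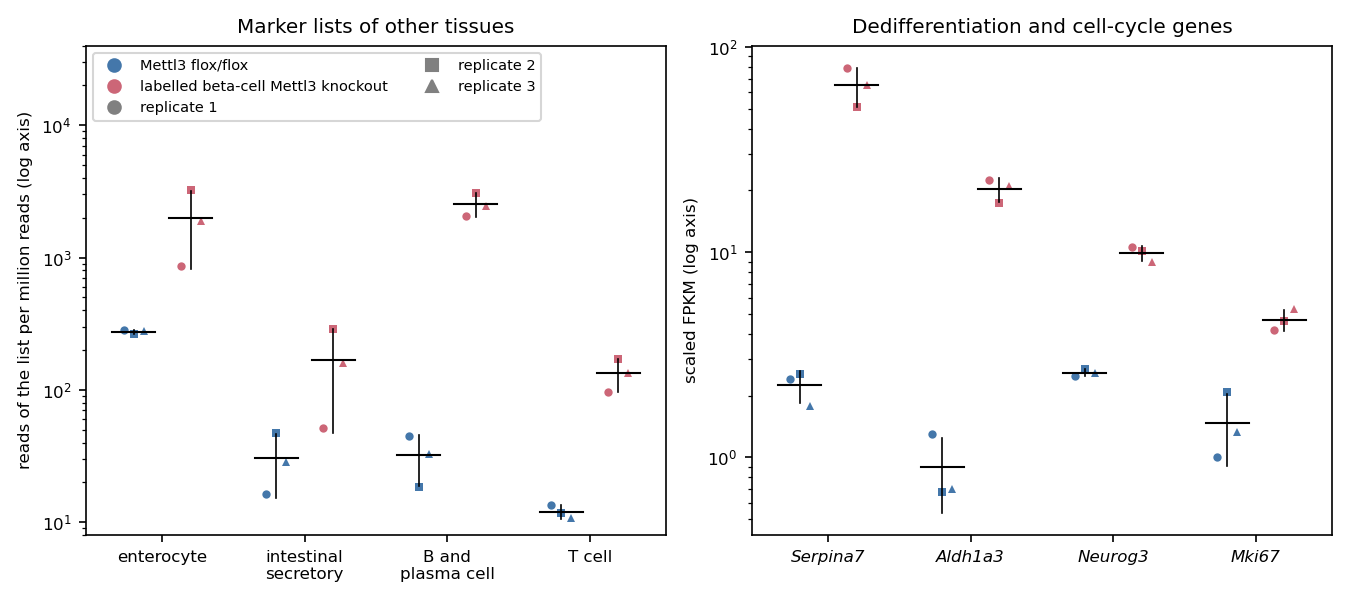
CPM (log axis, left) of 4 marker lists written after the values were seen, and scaled FPKM (log axis, right) of Serpina7, Aldh1a3, Neurog3 and Mki67, in flox/flox libraries (blue) and libraries labelled knockout (red), with a marker shape per replicate and lines for the mean and SD (n = 3 each). Enterocyte markers range from 868 to 3226 CPM over the libraries labelled knockout.

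Endothelial and acinar markers were lower. Of 17 endothelial markers 16 fell, 0 rose and 1 did not pass, as when adjusted over the list alone, with a median of -0.79. Esm1 and Emcn fell by 1.30 ± 0.09 and 1.13 ± 0.13 (SE, adjusted p = 0.000211 and 0.00129). The list's camera adjusted p was 1.26e-07, and it was an adjusted p = 0.529 with an estimated correlation. Of 29 acinar markers 17 fell, 0 rose and 12 did not pass (21 and 0 adjusted over the list alone). Scaled to each library's own reads, the acinar list came to 1286, 3892 and 2104 CPM in flox/flox replicates 1 to 3 and to 1414, 1055 and 1205 CPM in the others, so flox/flox replicate 2 stood highest and the groups overlapped. Cpb1, a pancreatic carboxypeptidase, fell by 1.80 ± 0.52 and Cel, a lipase, by 1.67 ± 0.45 (adjusted p = 0.0379 and 0.0289). Both calls were lost without flox/flox replicate 2 or 3, or labelled-knockout replicate 2 or 3 (adjusted p = 0.0878 to 0.0962 for Cpb1 and 0.0651 to 0.0787 for Cel). In camera the adjusted p was 0.000551, an adjusted p = 0.806 with an estimated correlation, and fry gave an adjusted p = 0.186.

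Mitochondrially encoded mRNAs were lower, with 12 of 13 falling and a median log2 difference of -1.81, as when adjusted over the list alone. The subunits mt-Co3 and mt-Atp6 fell by 1.92 ± 0.23 and 2.02 ± 0.31 (SE, adjusted p = 0.00169 and 0.00393), although nuclear copies of mitochondrial genes can take or lend reads. The mitochondrial genome took 8.12% to 12.6% of reads in flox/flox libraries and 3.04% to 5.36% in the others (exact two-sided permutation p = 0.10). By camera the adjusted p was 9.83e-07, and it was an adjusted p = 0.55 with an estimated correlation. Of 38 nuclear genes for oxidative phosphorylation 8 fell, 3 rose and 27 did not pass (6 and 1 adjusted over the list alone), with a median of -0.09 and a camera adjusted p = 0.353.

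Cell-cycle genes were higher, with 18 of 26 rising, 0 falling and 8 not passing (19 and 0 adjusted over the list alone). Mki67, a proliferation marker, rose from 1.47 ± 0.561 to 4.68 ± 0.538 scaled FPKM and Bub1b, a mitotic checkpoint kinase, from 0.491 ± 0.0746 to 2.19 ± 0.289 (SD, n = 3 each; adjusted p = 0.0034 and 0.00189), in the libraries in which lymphocyte and intestinal markers rose, so the cells these reads came from are not known. The list's camera adjusted p was 6.23e-08, and it was an adjusted p = 0.55 with an estimated correlation. With a filter at 5 FPKM that call was lost (adjusted p = 0.103). In the inflammatory list 8 of 13 rose, 1 fell and 4 did not pass (8 and 2 adjusted over the list alone). Ccl5, a chemokine made by T cells among others, rose by 3.50 ± 0.49, in the libraries in which lymphocyte markers rose, and Tnfaip3 by 1.20 ± 0.14 (SE, adjusted p = 0.00297 and 0.00139). Its camera adjusted p was 0.0223, and it was an adjusted p = 0.55 with an estimated correlation. The call was also lost with a filter at 5 FPKM, with own-total scaling and without labelled-knockout replicates 2 and 3 (adjusted p = 0.266, 0.171 and 0.0758).

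In the p53 and apoptosis list 8 of 25 rose, 2 fell and 15 did not pass (11 and 3 adjusted over the list alone). Pmaip1, a pro-apoptotic BH3 protein, rose by 1.68 ± 0.24 and Plk2 fell by 1.01 ± 0.07 (SE, adjusted p = 0.00306 and 0.000257). In camera the adjusted p was 0.0327, and the call was lost with an adjusted p = 0.529 with an estimated correlation and without flox/flox replicate 1 or 3 (adjusted p = 0.0698 and 0.0551). A filter at 5 FPKM and own-total scaling also ended it (adjusted p = 0.177 and 0.205). Of 55 cytosolic ribosomal protein genes 4 rose, 0 fell and 51 did not pass, and 0 passed adjusted over the list alone. Rps12 rose by 0.51 ± 0.15 (adjusted p = 0.0408) and lost its call without any flox/flox library or without labelled-knockout replicate 1 or 2 (adjusted p = 0.0758 to 0.112). By camera the adjusted p was 0.0163, and the call was lost with an adjusted p = 0.806 with an estimated correlation and without flox/flox replicate 2, flox/flox replicate 3 or labelled-knockout replicate 1 (adjusted p = 0.0672, 0.0645 and 0.14), and fry gave an adjusted p = 0.237.

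**Figure D3:**
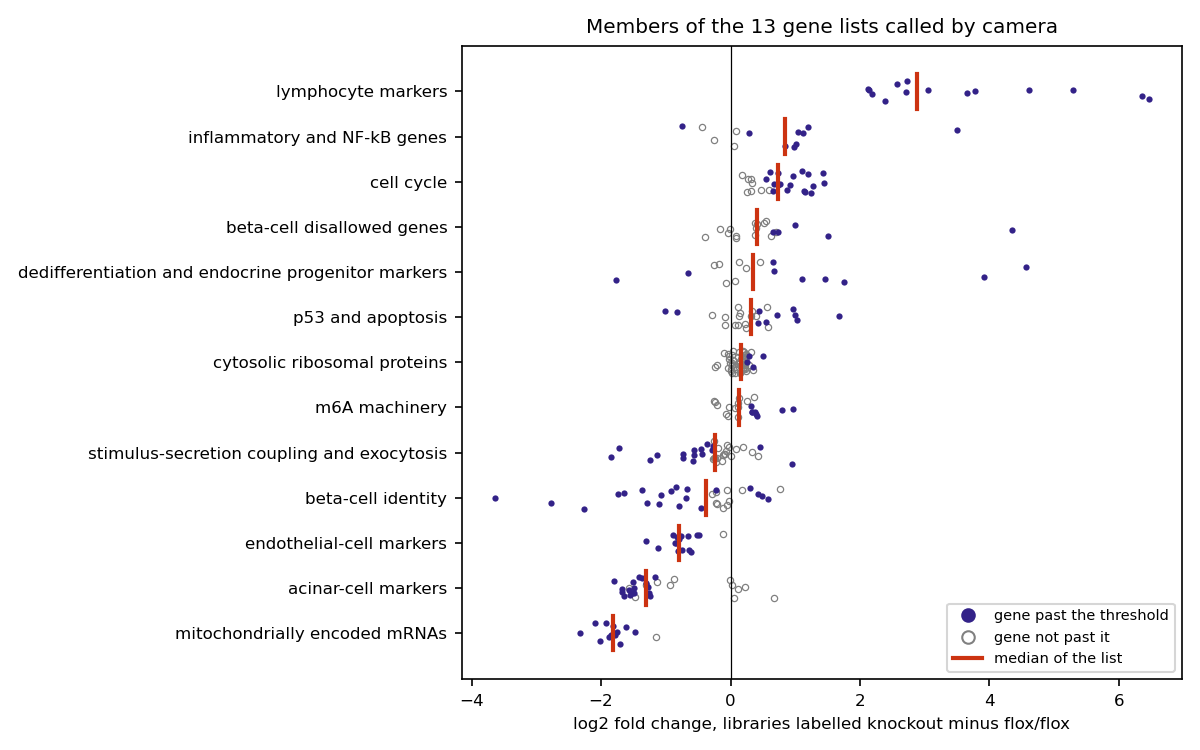
Log2 differences (libraries labelled knockout minus flox/flox, horizontal axis) of the tested members of the 13 gene lists called by camera, with filled points past the threshold, open points not past it and a red line at each list's median. Medians run from -1.81 for mitochondrially encoded mRNAs to 2.88 for lymphocyte markers.

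Over all 14497 tested genes, 2446 were higher and 2489 lower in the libraries labelled knockout, 4935 in total, of which 745 rose and 384 fell by at least 1 on the log2 scale. The groups did not overlap for 50.5% of tested genes, against 10% by chance. The largest falls included Cox6a2, a subunit of cytochrome c oxidase (-3.74 ± 0.22 SE, adjusted p = 0.000151), P2ry6, a nucleotide receptor (-2.64 ± 0.10, adjusted p = 3.26e-05), Prss53 (-2.76 ± 0.08, adjusted p = 1.86e-05) and the unnamed locus AC121860.1 (-2.97 ± 0.17, adjusted p = 0.000133). An unannotated locus on chromosome 1 from 184169111 to 184176146 fell by 2.64 ± 0.16 (adjusted p = 0.000158). Mir344i, with 1 to 3 reads per library labelled knockout, completed the 8 together with Mafa and Trpm5. Prss53 overlaps Zfp646 on the opposite strand and Gm21974 on its own, and Cox6a2 overlaps Itgad on the opposite strand, so their reads may be shared. With each library scaled to its own reads the calls became 7643 higher and 709 lower, and without labelled-knockout replicate 3 there were 2710 calls. Leaving out labelled-knockout replicates 2 and 3, those with the most enterocyte reads, left 1105 calls, and ended 76 of the 137 calls of named genes, among them Ins1, Nkx6-1 and Mki67 (adjusted p = 0.363, 0.0586 and 0.116). Their log2 differences were then -1.71, -0.60 and 1.29, against -1.74, -0.69 and 1.43 in the main fit, so with 1 library on that side a lost call does not by itself tie a change to intestinal reads.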

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

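The tests on the 3 patterns below were chosen after the results were seen, and the count of other splits was planned before. Groups of 3 libraries were not tested for outlying values. Gh, the growth hormone gene, is outside the tested genes because its level was below the filter, and it had 5, 2 and 7 reads in labelled-knockout replicates 1 to 3, 14 in total, against 0 in the 3 flox/flox libraries (a floor of 3 reads). The other splits of the 6 libraries, 10 in all with the real one, are too few for a share under 0.05. The real split gave 4935 calls, the highest other gave 0, and 1 of the 10 splits reached the real count.

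Intestinal and lymphoid transcripts were higher in the libraries labelled knockout. Intestinal tissue carried over during islet isolation is a candidate explanation: 100% of the 28 enterocyte markers with at least 20 reads, and 12 of 14 secretory-cell markers, were highest in replicate 2 and lowest in replicate 1, an order noticed before it was tested and also found in 51.4% of the variable genes of that group. Only 14 of the 19 listed secretory-cell markers had that many reads, and 7 of the 11 tested rose. Muc2 and Zg16 are named here after their values were seen. Muc2 had 0, 0 and 3 reads in labelled-knockout replicates 1 to 3. Zg16, although in that order, did not rise (log2 difference 0.02, limma adjusted p = 0.976). It was already at 11.3, 37.8 and 21.3 FPKM in flox/flox replicates 1 to 3. The acinar list had the same order there, with 1286, 3892 and 2104 CPM. Zg16 reads may thus have more than 1 source, so its lack of a rise cannot decide on carry-over. Of the tested intestinal smooth-muscle markers, 0 of 4 rose. One source adding enterocyte transcripts and those of T cells and of B cells other than plasma cells in fixed proportions is argued against, since the median log2 ratio of replicate 2 to replicate 1 was 3.31 for enterocyte markers, -0.75 for 6 selected B-cell markers and 0.77 for 15 T-cell markers, 4.06 and 2.55 below the enterocyte value, with SDs over genes of 1.33, 0.25 and 0.62. Intestinal genes switched on in islet cells by the genotype cannot be told apart from carry-over, because enterocyte markers were above the flox/flox mean in replicate 1 as well (median log2 ratio 2.31, SD over genes 1.87) and whole-islet reads do not say which cells they came from. Intestinal tissue with a varying share of immune cells is not excluded, as the whole B-cell and plasma-cell list, immunoglobulin genes included, followed the enterocyte order with 2045, 3088 and 2461 CPM in labelled-knockout replicates 1 to 3, and where the lymphocytes came from stays open.

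β-cell genes were lower in the libraries labelled knockout. The granule list, shared by islet endocrine cells, had a median log2 difference of 0.30 (SD over genes 0.63) where the called-lower identity genes had -1.09. For those genes, dilution of islet cells by other tissue is argued against as the whole cause. They were picked because they fell in these data. The whole identity list had a median of -0.37, a gap little larger than that SD. Of 22 granule genes 9 rose and 4 fell. The comparison therefore does not decide on dilution for the whole identity list. A lower share of β cells as the whole cause is also argued against, since the 95% interval of Iapp starts at -0.64 while those of Mafa and Slc2a2 end at -2.26 and -2.11. The scaling moved the values and left most calls: with each library scaled to its own reads, 14 of the 16 genes were still lower and past the threshold, their median going from -1.09 to -0.68. The genotype stays open as an untested biological difference, as Mettl3 itself was not lower in these libraries, and a smaller β-cell share could still add to the pattern.

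Mitochondrially encoded mRNAs were lower in the libraries labelled knockout, with a median log2 difference of -1.81. The scaling is argued against as the whole cause, as the median was -1.41 with each library scaled to its own reads. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, named after their values were seen, did not pass with that scaling. Their log2 differences were 0.18 and -0.14 (limma adjusted p = 0.495 and 0.667). Both lay below the median of all tested genes with that scaling, 0.36, so they are not shown to be unchanged. Dilution by other tissue is argued against by the granule list's 0.30. RNA quality or handling cannot be told apart from the genotype: the lowest flox/flox share of mitochondrial reads was 1.52 times the highest of the other group, shares varied 1.55-fold and 1.76-fold within the groups, and no RNA quality value was analysed here.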

How the results depend on the processing

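Own-total scaling, voom, leaving out libraries 2 and 3 labelled knockout, and leaving out intestinal and lymphoid genes were chosen after seeing the data. Scaling FPKM as deposited applied 1 factor to every library and tested nothing. The cause was not tested where none is given. The 4935 calls (2446 higher, 2489 lower) became 3090 with a filter at 5 FPKM (1247 higher), where fewer genes were tested, 7639 with library weights (3724 and 3915), whose estimation stopped before converging, and 1129 with an absolute log2 difference of at least 1 (745 and 384). With each library scaled to its own reads there were 8352 calls (7643 and 709, or 91.5% higher against 49.6%), the median of all genes moved from -0.0045 to 0.3641, and Mettl3 passed at 0.6116 (adjusted p = 0.00421, against 0.0621 to 0.474 in the other alternatives that kept it). Relative to that shift Mettl3 changed little. Without labelled-knockout replicates 2 and 3 there were 1105 calls (581 and 524), with 30 of the markers of other cell types called against 90, and the lone library is assumed to vary like the others. Leaving out each library in turn gave 2710 to 4219 calls (1319 to 2078 higher, 1391 to 2141 lower) and 54 to 91 markers, lowest each time without labelled-knockout replicate 3. Without flox/flox replicate 3 there were 1635 lower calls and 58 markers. Camera with an estimated correlation called 0 lists, where camera called 13, fry 15 and fry's mixed test 30, and the smallest adjusted p was 0.308.

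Among 143 named genes, Iapp, which had not passed, reversed to 0.7477 with quantile normalization, where it passed (adjusted p = 0.00517), to 0.286 with own-total scaling and to 0.1433 without labelled-knockout replicates 2 and 3, and ranged from -0.2483 to 0.0206 without single libraries. Sst reversed to 0.4049 with quantile normalization, which holds Ins1 and Ins2 at 0 by construction, and Gcg ranged from -0.0494 to 0.3073 without single libraries. Msmo1, called lower, reversed to 0.0046 with own-total scaling. Hist1h2bc reversed to 0.1692 with own-total scaling and to 0.0309 without labelled-knockout replicates 2 and 3, and Hist2h2be to 0.0891 with own-total scaling; neither had passed. Of 137 called named genes, 97 were called in all 6 fits without 1 library. The replicate block gave 4659 calls and lost 8 of the named genes' calls, and no list's. Same-numbered libraries deviated together with correlations of 0.0811, 0.0751 and 0.0423, each the highest of its row, a hint from the data and not from the design, so the numbers were not taken as pairs. Depth limits genes with few reads, such as Mir344i and Gh.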

Other observations

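The test on exon structure was planned before its result was seen, and the test on growth hormone after. Secretory granule genes and insulin signalling genes moved in both directions in the libraries labelled knockout. Of 22 granule genes 9 rose, 4 fell and 9 did not pass, as when adjusted over the list alone (camera adjusted p = 0.158). Vgf, a granin family peptide precursor, rose by 1.46 ± 0.20 and Pam, which amidates peptides, by 1.11 ± 0.15 (SE, limma adjusted p = 0.00248 and 0.00235). Of 19 insulin and IGF signalling genes 5 rose and 5 fell (5 and 6 adjusted over the list alone). Irs2, an insulin receptor substrate, rose by 2.06 and Igfbp3 fell by 1.02 (adjusted p = 0.000584 and 0.000247), and the list's median was -0.06, its mean 0.05 and its test lower (adjusted p = 0.689). In the unfolded protein response list 3 of 32 rose and 5 fell, as when adjusted over the list alone (adjusted p = 0.353): the chaperone Pdia4 rose by 1.02 and Ddit3, a stress transcription factor, fell by 0.97 (adjusted p = 0.00457 and 0.000674). Of 25 genes of the TCA cycle and anaplerosis 5 fell and 2 rose (4 and 1 adjusted over the list alone; adjusted p = 0.434), with Pcx, pyruvate carboxylase, falling by 1.23 (adjusted p = 0.000197).

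Macrophage and dendritic-cell markers split, with 7 of 20 rising and 5 falling, as when adjusted over the list alone; the median was -0.07 while the mean was 0.21 and the test pointed up (camera adjusted p = 0.689). Ptprc, the pan-leukocyte CD45, rose by 2.27 and Lyz2 by 1.25 (adjusted p = 7.93e-05 and 0.00116). Stellate-cell and fibroblast markers split 7 higher and 5 lower of 16 (adjusted p = 0.968), with Dcn rising by 1.36 and Col6a3 falling by 1.12 (adjusted p = 0.00344 and 0.0137). The lists that camera did not call numbered 21. Of the tested members rising and falling there were 2 and 3 of 14 α-cell markers, 2 and 2 of 8 δ-cell markers, 3 and 0 of 7 PP-cell and epsilon-cell markers, 1 and 1 of 14 ductal markers, 0 and 2 of 7 Schwann-cell and neuronal markers, 0 and 2 of 3 adipocyte markers and 0 and 1 of 4 red blood cell genes. There were 5 and 1 of 31 interferon genes, 0 and 6 of 21 immediate early genes, 4 and 5 of 21 glycolysis genes, 4 and 3 of 21 NRF2 genes, 3 and 2 of 21 cholesterol synthesis genes, and 0 and 0 of 8 replication-dependent histone genes. Of the lists written after the values were seen, 7 of 11 intestinal secretory-cell, 17 of 17 B-cell and plasma-cell, 9 of 9 T-cell and 0 of 4 intestinal smooth-muscle markers rose.

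The median log2 ratio of labelled-knockout replicate 2 to replicate 1 over 26 cell-cycle genes was 0.104 (SD over genes 0.253), against 3.31 for enterocyte, 0.77 for T-cell and -0.75 for B-cell markers. Replicate 3 held the middle value in 75.4% of the 1315 most variable genes of the flox/flox group and in 85.4% of 2309 in the other group, against 33.3% for libraries with no structure. For the best mixture of replicates 1 and 2, the squared miss of replicate 3 was 3.08 and 2.91 times the sampling variance (median over genes). Neither was thus a plain sum of the other libraries' reads. The same measure was 3.48 and 5.12 for flox/flox replicates 1 and 2, and 4.95 and 4.64 for labelled-knockout replicates 1 and 2. Replicate 3 was therefore the closest to a mixture in each group. Pooled RNA is not excluded by this, so replicate 3 of either group may not be independent, and the p-values, which take 3 independent libraries per group, would then be too small.

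Deletion of an m6A writer was hypothesised to raise mRNAs with a long internal exon, where m6A sites are dense. Across 11089 protein-coding genes, which are not independent replicates, the rank correlation of the log2 difference with the longest internal exon was 0.087 with mean level and length held fixed. That is between the 0.05 and 0.1 set beforehand, so the test did not decide. With neither held fixed, the 760 genes with an internal exon of at least 1000 bases had a median log2 difference of 0.118, with 200 called higher and 86 lower, against -0.0489, with 632 higher and 910 lower, for the 4508 genes with none of 200 bases or more. The rank correlation with neither held fixed was 0.115. Flox/flox replicates 1 to 3, each against the other flox/flox libraries, then gave -0.032, -0.0549 and 0.115. A correlation as large thus arose with no difference in genotype. Holding both fixed, the correlation was 0.0607, 0.0993 and 0.0891 in labelled-knockout replicates 1 to 3. Flox/flox replicates 1 to 3, each against the other flox/flox libraries, gave -0.013, -0.0199 and 0.0411 with both held fixed.

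Some Cre transgenes carry a growth hormone sequence, which may raise genes that respond to lactogens. The labels name RIP-Cre and do not say whether this construct carries one. Gh had 5, 2 and 7 reads in labelled-knockout replicates 1 to 3 and 0 in each flox/flox library. Whether those few reads came from the transgene was not tested. Tph1, the serotonin-synthesis enzyme that lactogen signalling induces, reached at most 0.025 FPKM in a library labelled knockout, which argues against such signalling. Of 11 lactogen-responsive genes 3 rose and 5 fell, as when adjusted over the list alone, with a median of -0.28, a mean of 0.02 and a test pointing down (camera adjusted p = 0.367). Tnfrsf11b rose by 1.57 and Fmo1 fell by 0.89 (adjusted p = 0.0111 and 0.00257).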
